A study of Ictalurus furcatus with 16 samples.

How the data were processed

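Total RNA from testis was sequenced in 16 libraries, 4 for each of ages 2, 4, 7 and 9. Per the labels, RNA was extracted with a Zymo Quick-RNA kit and libraries were made with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.5, MultiQC 1.10.1, HTSeq 0.11.1 and edgeR 4.4.2; their roles and settings, including strandedness, are not given in the sources used here. The deposited values are raw counts of fragments, 1 table per library with 50072 transcripts and 5 summary lines. The summary lines (no feature, ambiguous, not unique and others) hold between 65.2% and 76.2% of the fragments and were left out of library sizes and tests. Counts are given per transcript, and between 22.8% and 29.4% of fragments were ambiguous, which includes fragments shared by transcripts of 1 gene; genes with several transcripts, paralogs and overlapping or antisense genes are therefore less certain.

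The counts were summed to the gene symbols that the deposited tables pair with the transcripts, giving 26356 genes, of which 16485 have 1 transcript. Gene names and biotypes were checked against a RefSeq gene table of the assembly Billie_1.0; 48916 of the transcripts matched it. Ages were taken from the labels. No library was a duplicate: the chi-square per degree of freedom between libraries of 1 age lay between 11.2 and 134.4. The labels describe the replicates as biological, so p-values measure the spread between fish, pooled over the 4 ages. The median variance of log2 CPM within an age was 0.369 at age 2, 0.183 at age 4, 0.181 at age 7 and 0.139 at age 9. The pooled spread therefore tends to understate that of age 2 and to overstate that of the older ages.

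Genes were kept by filterByExpr (a minimum count of 10 and a total of 15), leaving 15979. Normalization was by TMM (factors 0.773 to 1.13), and tests by edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with all 16 libraries in 1 model by age (12 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05, two-sided. The common biological coefficient of variation was 0.417. The trend used age as a number (14 residual degrees of freedom). Log2 CPM used a prior count of 2. A set of 32 gene lists was tested with limma 3.58.1 camera at a preset correlation of 0.01. It was repeated with the correlation estimated per list and with fry, which tests whether a list moves 1 way and does not compare it with other genes. Camera called 13, 9 and 10 lists at ages 4, 7 and 9 against age 2, fry 6, 4 and 5, and camera with an estimated correlation 0, so that no list call held with it. Among lists past camera against age 2 the median, mean and test had 1 sign.

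The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For each comparison against age 2 the rule took genes past the threshold with a mean of at least 1 CPM, a symbol that is not a LOC number and no overlap between the 2 ages. Among these it named the 10 largest changes in each direction. Up to 2 LOC genes in each direction were named under the same conditions apart from the symbol. The 4 list members with the smallest p per list were named without these conditions, so their ages may overlap. For comparisons with fewer calls the rule took the genes with the smallest p. Where a group held 1 to 3 counts a ratio with a 95% counting interval is given, and where it held 0 a bound against 3 counts over the group; both cover counting error only. In the smallest library 3 counts equal 0.584 CPM. The correlation planned over all libraries for principal component 1 was restricted to 1 cluster because the libraries fell into separate clusters. The count of genes without overlap over all tested genes was added after seeing the data. Permutation tests were exact or used 100000 resamples.

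The procedure was tested on simulated counts for age 9 against age 2 (15648 genes, 3 sets with 200 changed genes each). It recovered 7.07% of genes changed 2-fold, 55.6% of those changed 4-fold and 82.1% of those changed 8-fold. Of its calls 5.65% were false, and 1 set with no change gave at most 1 call in any comparison. Small changes were thus mostly missed at this sample size and spread. The simulated counts held no library that stood apart from its age, so the false calls that such a library may cause were not measured.

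The alternatives were an added limit on the log2 fold change, the size factors of DESeq2 1.42.0, upper quartile normalization, no filter or a CPM filter, the replicate number as a block, fits on 2 ages alone, DESeq2, limma voom with sample quality weights and the omission of each library in turn. Transcripts as deposited, the omission of ribosomal RNA and mitochondrial genes, and a trend over ages 4, 7 and 9 were added after seeing the data. Values were summarised with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genome coordinates were not used here.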

Results

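RNA was sequenced from the testes of 16 male blue catfish (Ictalurus furcatus), a North American freshwater fish. The labels give 4 ages (2, 4, 7 and 9, with no unit stated) and 4 fish per age, numbered as biological replicates, and the series' design names age 2 as the control. The series asks how the testis transcriptome differs with age. Each library held between 20541746 and 24732597 counted fragments, of which between 5136717 and 8081160 (23.8% to 34.8%) were assigned to a transcript. Of 26356 genes, 15979 had enough counts to be tested. The share of assigned fragments from nuclear ribosomal RNA was 21.2% ± 5.60 (SD, n = 4) at age 2, 10.8% ± 4.12 at age 4, 12.6% ± 2.702 at age 7 and 11.5% ± 1.14 at age 9 (n = 4 each). It was highest in age 2 replicate 1, at 28.3%, and between 14.8% and 22.2% in the other 3 age 2 libraries.

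Age 2 replicate 1 did not resemble the other 3 age 2 testes. On principal component 1, which held 62.4% of the variance of the 500 most variable genes, the other 3 lay between 56.0 and 77.9, and age 2 replicate 1 lay at -8.97, among the libraries of the older ages (-29.6 to 7.01). The mean log2 CPM of 75 sperm flagellum and spermiogenesis genes was 5.01 in age 2 replicate 1, between 1.96 and 2.61 in the other 3 age 2 libraries, and between 4.01 and 5.67 in the 12 older ones. The Sertoli cell gene gsdf, a growth factor of the fish gonad, stood at 101.5 CPM in age 2 replicate 1 and between 1934 and 6708 CPM in the other 3 age 2 libraries. Because 3 libraries stood apart on component 1, a correlation with age was computed only within the other 13. There it was r = -0.188 (permutation p = 0.542) and Spearman's rho = -0.135 (permutation p = 0.657), and r = 0.026 without the 2 libraries farthest from the median score. Each age 2 library lay on average 0.935 ± 0.382 log2 units (SD, n = 4) from the others of its age, against 0.679 ± 0.082 (SD, n = 12) in the older ages, a difference of 0.257 (exact permutation test over 1820 splits, two-sided, p = 0.032). The test shuffled finished distances, which depend on each other within an age, so this p and those below are approximate. Without age 2 replicate 1 the difference was -0.047 (exact permutation p = 0.365), so it rested on that library. The difference stayed between 0.231 and 0.242 but no longer passed without age 4 replicate 1 (exact p = 0.059) or replicate 2 (exact p = 0.055), age 7 replicate 1 (exact p = 0.071) or replicate 4 (exact p = 0.056), and age 9 replicate 1 (exact p = 0.056) or replicate 3 (exact p = 0.051).

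**Figure D1:**
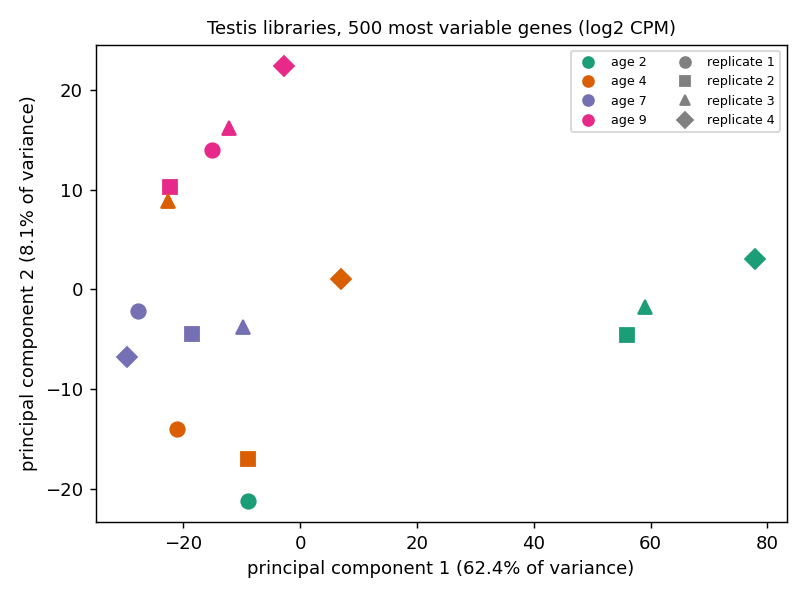
Scores of the 16 testis libraries on principal components 1 and 2 of log2 CPM over the 500 most variable genes, in arbitrary units with the percent of variance on each axis. Colour gives the age and symbol the replicate number. Age 2 replicates 2, 3 and 4 lie between 56.0 and 77.9 on component 1, and age 2 replicate 1 at -8.97.

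At age 4, compared with age 2, some genes of the sperm tail, of interferon and macrophage responses, of the respiratory chain and of the proteasome rose, and some of spermatogonia, growth factor signalling, the extracellular matrix and the ribosome fell. Most members of these lists did not pass, and no list passed with an estimated correlation. Of the 75 flagellum and spermiogenesis genes, 11 rose and 3 fell (14 and 3 adjusted over the list alone), with a median log2 fold change of 1.59. The ciliary assembly factor ccdc40 rose by 2.71 ± 0.60 (log2, SE), whereas the axonemal dynein dnah3 fell by 1.16 ± 0.28. Of 21 spermatogonia and germline genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone). Among these, nanos1, an RNA-binding regulator, fell by 4.02 ± 0.84 and tdrd1, of the piRNA pathway, fell by 1.92 ± 0.42. The flagellum and spermatogonia lists passed the set test, though both had an adjusted p = 0.633 with an estimated correlation. Age 2 replicate 1 moved with both groups. Its tdrd1 level was 120.4 CPM, within the range of 72.2 to 162.7 at age 4, while the other 3 age 2 libraries held between 387.9 and 703.4.

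The interferon response and macrophage genes that passed at age 4 were all higher. Of 21 interferon response genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), among them ifit8 (3.46 ± 0.70), the antiviral GTPase mxa (2.27 ± 0.50) and the RNA sensor dhx58 (1.40 ± 0.33). Of 26 macrophage and myeloid genes 7 rose and 0 fell (8 and 0 adjusted over the list alone), including csf3r, a colony stimulating factor receptor (1.49 ± 0.28), and the complement component c1qb (1.86 ± 0.44). Both lists had an adjusted p = 0.633 with an estimated correlation. Age 2 replicate 1 lay with its own age here. Its macrophage mean was 3.07, and all 4 age 2 libraries (3.07 to 3.48) lay below all 12 older ones (3.55 to 4.97). Its mean of smooth muscle and peritubular genes (3.71) was also the lowest of all libraries, though age 2 replicates 2 to 4 held 4.86 to 5.97. A low mean in this library therefore need not mark age 2. Of 16 lymphocyte genes 1 rose, rag2, and 0 fell (0 and 0 adjusted over the list alone), with a median of -0.06, and none of 15 erythrocyte genes passed edgeR's quasi-likelihood test.

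The growth factor, hormone receptor and matrix genes that passed at age 4 were all lower. Growth factor and IGF signalling had 14 of 37 genes lower and 0 higher (16 and 0 adjusted over the list alone), with the IGF receptor igf1rb (-1.13 ± 0.20) and irs1 (-1.38 ± 0.26). Hormone receptors had 4 of 12 lower and 0 higher (8 and 0 adjusted over the list alone), led by the androgen receptor ar (-2.08 ± 0.38). Both lists had an adjusted p = 0.633 with an estimated correlation. Of 47 extracellular matrix genes 13 fell and 0 rose (16 and 1 adjusted over the list alone), with the collagen col1a2 at -2.01 ± 0.47 (adjusted p = 0.914 for the list with an estimated correlation). Other cell type lists had falls without passing camera. Of 19 smooth muscle and peritubular genes 6 fell and 0 rose (6 and 0 adjusted over the list alone), though at age 7 only 1 fell and 1 rose and at age 9 4 rose and 0 fell. Of 9 kidney, gut and pancreas epithelium genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; fry adjusted p = 0.039), with 4 lower at age 7 and 5 at age 9. Among 73 ribosomal protein genes 18 fell and 0 rose (23 and 0 adjusted over the list alone), with an adjusted p = 0.744 with an estimated correlation. Nuclear genes of oxidative phosphorylation (11 of 45 higher, 16 adjusted over the list alone, for example ndufc2 at 1.25 ± 0.25) and of the proteasome (10 of 36 higher, 16 adjusted over the list alone, for example psmb3 at 1.32 ± 0.34) had 0 lower members. Both had an adjusted p = 0.633 with an estimated correlation. The remaining lists past the set test were immediate early and handling stress genes (0 of 38 higher, 6 lower, 5 lower adjusted over the list alone; adjusted p = 0.856 with an estimated correlation), heat shock genes (6 of 50 higher, also 6 adjusted over the list alone; adjusted p = 0.725 with an estimated correlation) and mitotic genes (7 of 62 higher, 2 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). In age 2 replicate 1 the growth factor list mean was 4.17. The other 3 age 2 libraries held 5.26 to 5.81 and the older ones 4.155 to 5.01. Its hormone receptor (3.41) and matrix (4.395) means were the lowest of all 16 libraries, while the other 3 of age 2 held 4.67 to 5.04 and 5.21 to 6.215. Its oxidative phosphorylation (4.699) and proteasome (6.18) means lay within the older ranges. The other 3 of age 2 held 3.69 to 3.93 and 4.94 to 5.15. Its col1a2 (287.4 CPM) lay within the age 4 range (151.9 to 344.7). These list differences therefore rested on age 2 replicates 2 to 4.

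**Figure D2:**
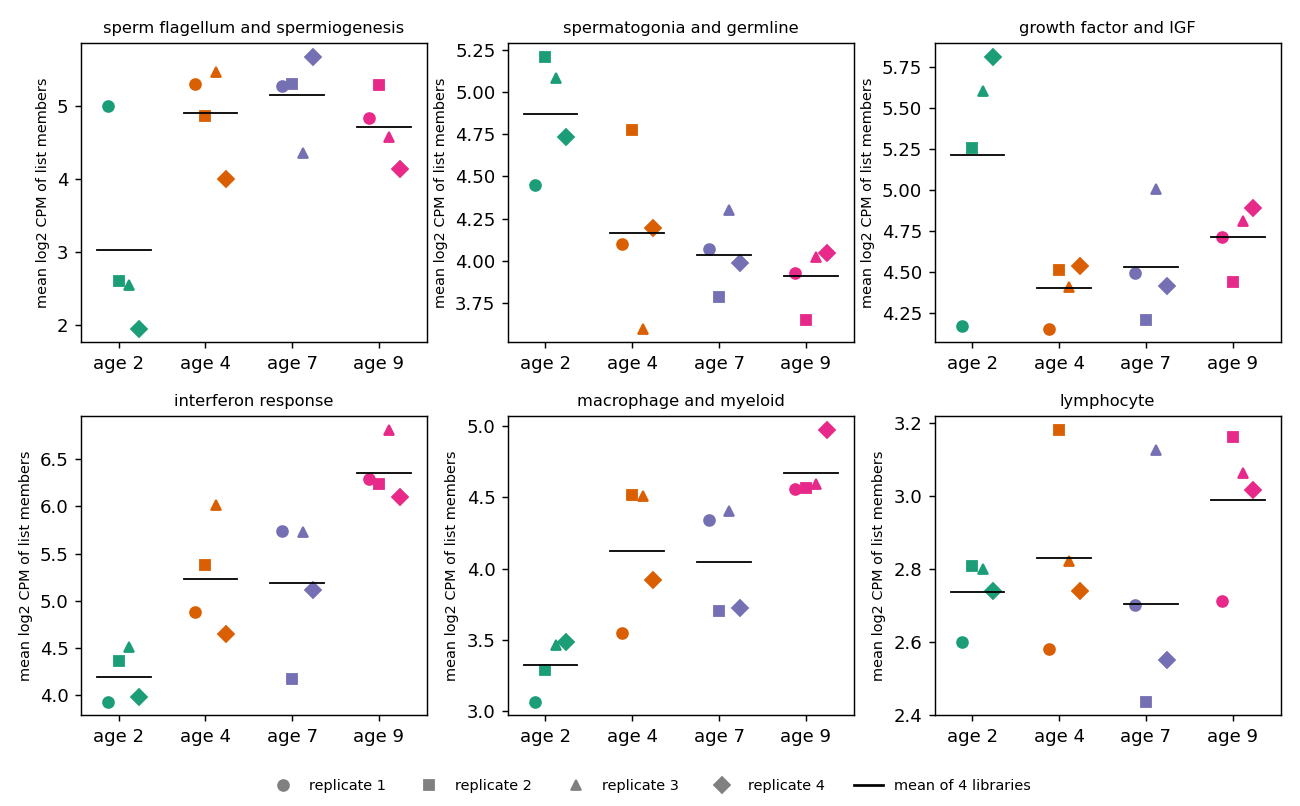
Mean log2 CPM of the members of 6 gene lists in each library, by age, with the replicate number as symbol and the mean of 4 libraries as a line; the vertical axes differ. For flagellum genes age 2 replicate 1 (5.01) lies with the older libraries, and for macrophage genes all age 2 libraries (3.07 to 3.48) lie below the rest.

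In all, 2979 genes passed at age 4 against age 2 by edgeR's quasi-likelihood test, 1065 higher and 1914 lower. Over all tested genes, whatever their p, all 4 libraries of one age lay above all 4 of the other in 1504 (9.41%, against 2.86% by chance), of which 983 passed. The largest rises among named genes without overlap were those of prok2, a secreted peptide of endocrine and immune signalling (log2 fold change 4.12 ± 1.32, from 2.34 ± 2.59 to 40.96 ± 40.08 CPM, SD, n = 4), and the steroid enzyme hsd17b1 (3.73 ± 1.05), followed by ift81, insl5b, ifit8, mycla, top3a, tmprss2 and upf3a (2.95 to 3.59). The kinase gene adck1 had 2 counts at age 2 and 19 at age 4, a ratio of 9.15 (95% counting interval 2.21 to 81.0). The largest falls without overlap were in the signalling ligand wnt9b (-4.93 ± 0.92, from 46.5 ± 50.6 to 1.495 ± 0.516 CPM), the channel best4 (-4.03 ± 0.66), hs3st2 and spon1a, then camk2n2, xkr6b, skor2, mab21l1, ptprua and ppp2r5b (-3.24 to -2.73). Among genes without a symbol, LOC128618436 was -4.39 ± 0.81. The count fell to 1 without age 4 replicate 3 (LOC128616375, named after its value was seen), 158 without age 2 replicate 3, 432 without age 2 replicate 4, 622 without age 4 replicate 1, 636 without age 2 replicate 2 and 1694 without age 4 replicate 2, and rose to 7581 without age 2 replicate 1. The excess of falls also rested on that library, as without it 3875 genes were higher and 3706 lower. Fitted on the 8 libraries of the 2 ages alone, edgeR called 0.

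**Figure D3:**
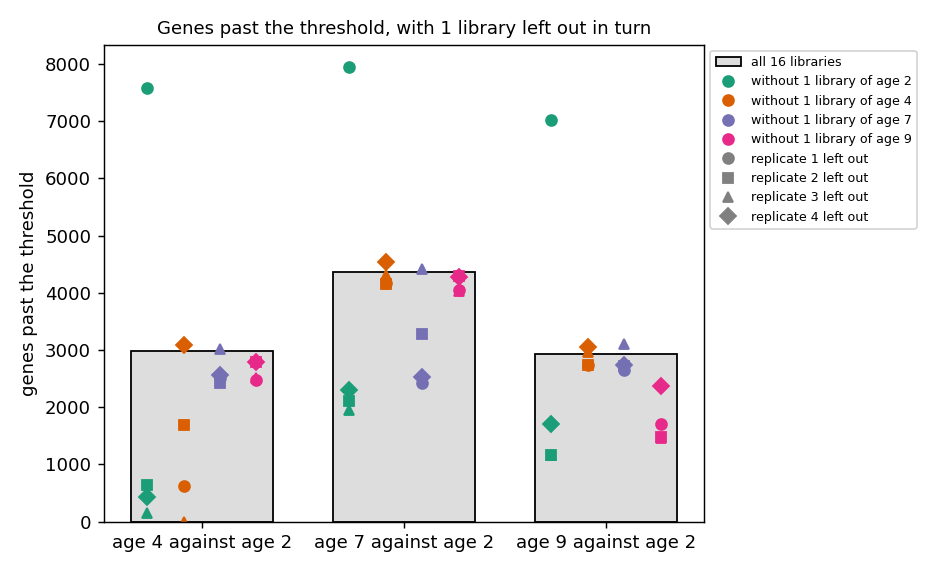
Number of genes past an adjusted p of 0.05 in the comparisons against age 2 with all 16 libraries (bars, from 0) and with 1 library left out in turn (points; colour gives the age and symbol the replicate left out). Without age 2 replicate 1 the counts are 7581, 7941 and 7028, above each bar.

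At age 7 the sperm tail genes that passed were mostly higher than at age 2, and the spermatogonia and growth factor genes that passed were mostly or all lower. Of the 75 flagellum genes 31 rose and 4 fell (43 and 5 adjusted over the list alone), with a median of 1.85. Here spata18 rose by 3.70 ± 0.89 and the dynein dnah9 fell by 1.76 ± 0.34. Of 21 spermatogonia and germline genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), including nanos2, a marker of undifferentiated spermatogonia (-4.96 ± 0.99), id4 (-2.64 ± 0.47) and tdrd1 (-2.31 ± 0.43). Interferon response genes rose in 9 of 21 cases and fell in 0 (9 and 0 adjusted over the list alone), and macrophage genes rose in 6 of 26 and fell in 0 (3 and 0 adjusted over the list alone). These 4 lists had an adjusted p = 0.838 with an estimated correlation. In age 2 replicate 1 nanos2 stood at 1.92 CPM, against 26.2 to 93.0 in the other 3 age 2 libraries and 0.667 to 1.39 at age 7. Nuclear oxidative phosphorylation genes rose in 11 of 45 cases and fell in 0 (8 and 0 adjusted over the list alone), proteasome genes in 5 of 36 and 0 (2 and 0 adjusted over the list alone), and heat shock genes in 11 of 50 and 2 (12 and 2 adjusted over the list alone). Each of these had an adjusted p = 0.838 with an estimated correlation. Growth factor genes fell in 11 of 37 cases and rose in 0 (16 and 0 adjusted over the list alone), and ribosomal protein genes fell in 10 of 73 and rose in 0 (1 and 0 adjusted over the list alone). Both had an adjusted p = 0.873 with an estimated correlation. Steroidogenic genes did not move as a group: 2 of 13 Leydig cell genes rose and 1 fell (2 and 1 adjusted over the list alone), with insl3, a peptide hormone of Leydig cells, at 4.56 ± 1.16, hsd17b1 at 4.27 ± 1.06 and the reductase srd5a1 at -1.90 ± 0.41. Their list median was -0.02 and their mean 0.54.

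Against age 2, 4368 genes passed at age 7, 1830 higher and 2538 lower, and 2414 of all tested genes had no overlap between the ages (15.1%, against 2.86% by chance), of which 1873 passed. Among named genes without overlap, the largest rises were those of exosc1 (4.00 ± 0.79), cabp2a (3.64 ± 0.60), ccdc13 (3.56 ± 0.87), mycla, ifit8, tppp3, insl5b, yjefn3 and tmem30c (3.22 to 3.35 for the last 6). For adck1, with 2 counts at age 2 and 42 at age 7, the ratio was 23.0 (95% counting interval 5.98 to 196.1). The largest falls without overlap were wnt6b (-5.06 ± 1.12), nanos2, qrfprb (-4.46 ± 0.84), vgll2b, kif26aa, klf5l, htr5aa, uts2r3, tubb2 and hpxa (-3.59 ± 0.64). Without a symbol, LOC128623107 rose by 5.58 ± 0.75, from 2.51 ± 1.22 to 121.3 ± 58.5 CPM. The count was 7941 (4021 higher, 3920 lower, so without the excess of falls) without age 2 replicate 1, 2113 without age 2 replicate 2, 1945 without age 2 replicate 3, 2308 without age 2 replicate 4, 2425 without age 7 replicate 1 and 2530 without age 7 replicate 4. On the 8 libraries of the 2 ages alone it was 795.

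At age 9 the interferon response stood out. Of its 21 genes 16 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 1.86. In particular, ifit8 rose by 4.98 ± 0.75 (11.04 ± 5.82 to 350.0 ± 153.8 CPM, SD, n = 4), mxa by 4.01 ± 0.53 (12.9 ± 3.76 to 208.1 ± 106.6), cmpk2 by 4.30 ± 0.65 and dhx58 by 2.94 ± 0.35. Macrophage and myeloid genes rose in 13 of 26 cases and fell in 0 (16 and 0 adjusted over the list alone), including the scavenger receptor marco (3.39 ± 0.64), csf3r (1.81 ± 0.28) and the transcription factor irf8 (2.05 ± 0.38). Both lists had an adjusted p = 0.511 with an estimated correlation. The interferon mean of all 4 age 9 libraries (6.10 to 6.81) lay above that of every other library, and age 2 replicate 1 had the lowest of all 16, at 3.93. Among 16 lymphocyte genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.03. Spermatogonia and germline genes fell in 9 of 21 cases and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.571 with an estimated correlation), and ribosomal protein genes fell in 20 of 73 and rose in 0 (33 and 0 adjusted over the list alone; adjusted p = 0.840 with an estimated correlation). For the flagellum list the median was 1.34 but only 4 of 75 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.840 with an estimated correlation). Immediate early and handling stress genes fell in 10 of 38 cases (12 adjusted over the list alone, with 1 higher), DNA repair and telomere genes in 9 of 48 (9 adjusted over the list alone, including atr at -1.18 ± 0.23) and growth factor genes in 8 of 37 (11 adjusted over the list alone). Oxidative phosphorylation genes rose in 5 of 45 cases (5 adjusted over the list alone), and 0 of 36 proteasome genes passed although their list did. These 5 lists had an adjusted p = 0.840 with an estimated correlation.

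**Figure D4:**
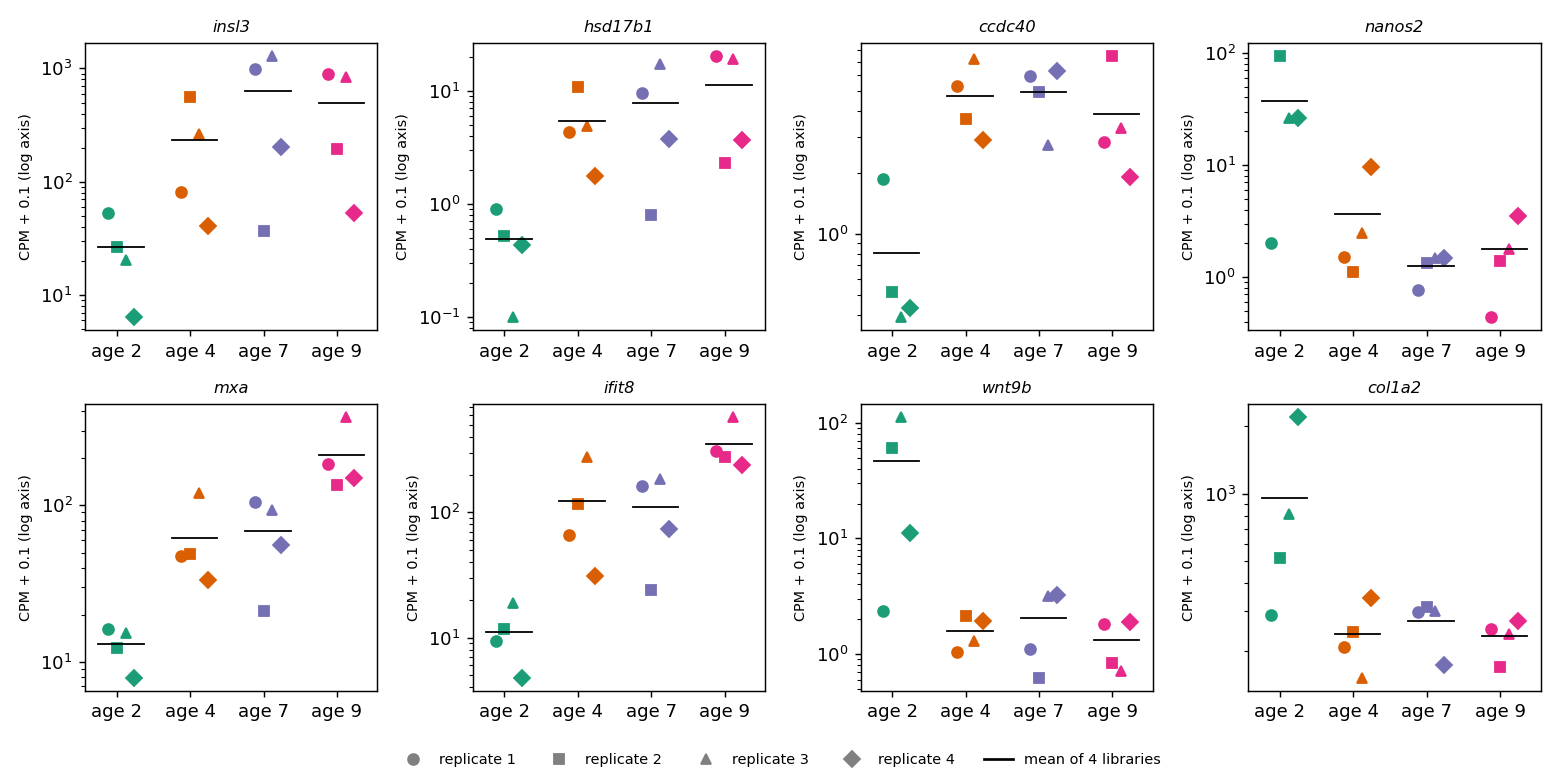
Normalized CPM plus 0.1, on a log axis, of 8 genes in each library by age, with the replicate number as symbol and the mean of 4 libraries as a line. The means of mxa and ifit8 are highest at age 9. For ifit8 the highest age 4 library (276.4 CPM) lies above the lowest of age 9 (238.7 CPM). Within age 7 insl3 spans 36.7 to 1278 CPM.

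Against age 2, 2934 genes passed at age 9, 1090 higher and 1844 lower, and 2405 of all tested genes had no overlap between the ages (15.05%, against 2.86% by chance), of which 1590 passed. Among named genes without overlap, the largest rises after ifit8 were hsd17b1 (4.80 ± 1.06), isg15, an interferon-induced ubiquitin-like protein (4.79 ± 0.99), helz2a, cmpk2, insl3 (4.22 ± 1.15, from 26.6 ± 19.6 to 495.7 ± 433.2 CPM), mxa, arsia and tnn. For adck1, with 2 counts at age 2 and 39 at age 9, the ratio was 21.4 (95% counting interval 5.54 to 182.9). The largest falls without overlap were in the ephrin receptor epha8 (-7.01 ± 0.98, from 72.3 ± 49.8 to 0.541 ± 0.305 CPM), wnt9b (-5.24 ± 0.95), gdpd3a, klf5l, best4, fam189b, cckar and loxl4 (-4.44 to -3.75 for the last 6). dtx3lb.2 had 95 counts at age 2 and 0 at age 9, at least 28.9-fold lower against a floor of 3 counts over the group, and hpxa had 84 and 2 counts, a ratio of 38.3 (95% counting interval 10.3 to 321.3). In age 2 replicate 1 epha8 was at 1.44 CPM, against 78.7 to 116.7 in the other 3 age 2 libraries. Its insl3 was 53.06 CPM, just below the lowest age 9 library (53.22), against 6.35 to 26.8 in the other 3. The count was 7028 (3602 higher, 3426 lower, so without the excess of falls) without age 2 replicate 1, 1158 without replicate 2, 1157 without replicate 3 and 1705 without replicate 4 of that age, and 1701, 1477 and 1470 without age 9 replicates 1, 2 and 3. On the 8 libraries of the 2 ages alone it was 987.

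Between the older ages few genes passed. This does not show that few differed, as the pooled spread includes the wider age 2 and small changes were mostly missed in the simulated counts. Fitted on the 8 libraries of the 2 ages alone, edgeR called 3 genes for age 7 against age 4, 8 for age 9 against age 4 and 6 for age 9 against age 7. At age 7 against age 4, 2 genes passed edgeR's quasi-likelihood test, both higher: LOC128623107, with a mean of 4.58 CPM at age 4 and 121.3 at age 7, and LOC128618010, with 2.92 and 74.8. They were named after their values were seen. In this comparison 623 genes had an unadjusted p under 0.05, DESeq2 called 13 and limma voom 0. At age 9 against age 4 edgeR called 0 genes (1505 at an unadjusted p under 0.05), DESeq2 108 and limma voom 63, and at age 9 against age 7 edgeR called 0 (1131 unadjusted), DESeq2 62 and limma voom 241. Camera called 4 lists at age 7 against age 4, 13 at age 9 against age 4 and 12 at age 9 against age 7, and none with an estimated correlation or by fry. At age 9 against age 4 these included smooth muscle, endothelial and macrophage genes (higher) and meiosis and DNA repair genes (lower), each with an adjusted p = 0.482 with an estimated correlation. Mitotic and proteasome genes were lower in the same test (both adjusted p = 0.554 with an estimated correlation). No member of these 7 lists passed over all genes; adjusted over the list alone, 3 endothelial genes rose and 1 proteasome gene fell. Of the 21 interferon response genes, adjusted over the list alone, 15 were higher at age 9 than at age 4 (median 1.15; adjusted p = 0.482 for the list with an estimated correlation) and 12 higher than at age 7 (median 1.29; adjusted p = 0.638 with an estimated correlation), while 0 passed over all genes. The symbols with the smallest p, none past the threshold, were myo15b (1.77 ± 0.30, adjusted p = 0.1197) for age 9 against age 4, igsf9b and dhx58 (1.42 ± 0.31 and 1.48 ± 0.33, both adjusted p = 0.343) for age 9 against age 7, and mthfd1l (-0.93 ± 0.21, adjusted p = 0.682) for age 7 against age 4. For age 7 against age 4 the count was 1 (LOC128618010) without age 9 replicate 2, age 7 replicate 3 or age 2 replicate 2, and 0 without age 9 replicates 3 or 4, age 7 replicates 1 or 4, any age 4 library or age 2 replicate 3. For age 9 against age 4 it was 1 without age 9 replicate 1, 8 without age 9 replicate 2 and 2 without age 7 replicate 2, and for age 9 against age 7 it was 1 without age 7 replicate 2 or age 2 replicate 1.

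Over all 4 ages, 3086 genes differed by 1 test of any difference, with epha8, slc9a6b, kif26aa, klf5l and dhx58 at the smallest p. A linear trend over age passed for 1992 genes, 514 rising and 1478 falling. limma voom with sample quality weights called 325, with the balance turned (203 rising, 122 falling). The cartilage matrix gene comp rose by 0.54 ± 0.07 log2 per unit of age, dhx58 by 0.36 ± 0.05 and myo15b by 0.28 ± 0.04, while unc119b fell by 0.36 ± 0.05, klf5l fell by 0.65 ± 0.08 and hpxa fell by 0.71 ± 0.09. Over ages 4, 7 and 9 alone, a fit chosen after seeing the data, edgeR called 0 genes for a trend (2078 at an unadjusted p under 0.05). The count for any difference was 7616 without age 2 replicate 1, 1061 without replicate 2, 851 without replicate 3 and 1245 without replicate 4 of that age, and the trend count 665, 705 and 1163 without age 2 replicates 2, 3 and 4.

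The comparisons against age 2 shared many calls, and they also share their control libraries. At ages 4, 7 and 9 together 1600 genes moved in the same direction, 503 higher and 1097 lower. At ages 4 and 7, 2391 genes were called in the same direction, where independent lists would share 426.0 and simulated unchanged groups 0. At ages 4 and 9 the numbers were 1725, 293.5 and 0, and at ages 7 and 9 they were 2212, 417.7 and 0. The covariance of the log2 fold changes was 1.11, 0.963 and 1.11 in these pairs, against 0.124, 0.124 and 0.124 in the simulations. The simulations drew all libraries around 1 mean per gene, with no library standing apart, and such sets give almost no calls. Neither simulated value can therefore show how much overlap the uneven age 2 libraries create. With the age 2 libraries split into separate pairs, so that no control was shared, the calls in common averaged 12, 66.8 and 84.8 over 6 such fits. They ranged from 0 to 69, 0 to 192 and 0 to 224, so they depended on which age 2 libraries were paired. Each comparison then had only a pair of controls, and age 2 replicate 1 was always in 1 of the pairs, which tends to leave fewer calls. The drop therefore cannot show how much overlap came from the shared controls.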

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

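The tests of explanations below were chosen after the results had been seen; the counts over other splits of the libraries follow a fixed rule but were also read after the real counts.

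Within ages, 11 of 160 groups of 4 values tested held 1 library far from the others, where chance gives about 1 in 20 groups (8). In age 2 this was replicate 1 for ccdc40 (1.76 CPM, next 0.417; gap 0.915 of the range), btg4 (8.34 CPM, next 0.291; 0.985) and slbp2 (8.82 CPM, next 1.46; 0.868). At age 4 replicate 4 had the highest nanos2 (9.47 CPM, next 2.37; 0.840) and crabp1a (4.88 CPM, next 1.19; 0.902). At age 7 replicate 4 had the lowest col1a2 (172.9 CPM, next 296.6; 0.873) and marco (5.01 CPM, next 12.5; 0.851). At age 9 replicate 1 had the lowest ambiguous share (25.8%, next 27.8%; 0.952), replicate 3 the highest btg4 (1.84 CPM, next 0.342; 0.904), and replicate 4 the highest tdrd1 (143.5 CPM, next 77.3; 0.909) and macrophage mean (4.97, next 4.59; 0.924).

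Age 2 replicate 1 lies with the older libraries in the means of the flagellum, spermatogonia and growth factor lists. An exchange of labels with an older library would leave a partner closer to age 2 than to its own age, and 0 of the 12 older libraries were. Its high ribosomal RNA share stays open: leaving out the 21 tested ribosomal RNA and mitochondrial genes moved its mean correlation with the other age 2 libraries only from 0.793 to 0.791, so an effect of RNA or library quality on the other genes was not tested. A single wrong label stays open too: joined to the other 3 age 2 libraries, it ranked 5 of 13 by the number of genes separating the set from the rest (509, while joining age 9 replicate 4 gave 1460), and its interferon and macrophage means were the lowest of all libraries. Its Sertoli cell (4.06) and smooth muscle (3.71) means were the lowest as well, while the other 3 age 2 libraries held 5.02 to 5.57 and 4.86 to 5.97. Its low interferon and macrophage means thus do not decide whether it belongs to age 2. No biological explanation was tested, as the design holds no other group that would account for it; a fish of age 2 further into sperm production remains possible.

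Interferon genes were higher at age 9 than at age 2. More lymphocytes cannot be excluded: the median of their list was 0.0342, below that of interferon genes (permutation p = 0.0007 over genes), but its members went both ways, with rag2 (2.04), itk (1.90), lat (1.48) and lck (1.44) higher, foxp3b lower (-3.29), and cd8a and cd79a at 0.01. More macrophages cannot be excluded either, with a median of 1.18 against 1.86 for interferon genes and a permutation p = 0.167 for the difference. A single fish of age 9 is argued against, since at least 13 of 21 genes still rose without any 1 of its libraries. An exposure shared by the fish of age 9 cannot be told apart from age in this design and was not tested.

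Many genes passed against age 2 (2979, 4368 and 2934 at ages 4, 7 and 9). Counting by transcript is argued against, because at least 19.7% of genes with 1 annotated transcript were called in each comparison, more than among genes with several (15.5% at age 4). The higher ribosomal RNA share at age 2 stays open: at least 90.7% of the calls were shared with the fit without ribosomal RNA and mitochondrial genes, but that fit moved the log2 fold changes by a median of 0.02 to 0.05, less than their median SE of 0.39, so it decides little. Library values speak against it as the whole cause, though single libraries do not exclude it: age 2 replicate 1 had the highest share (28.3%) but lay at -8.97 on component 1, and age 2 replicate 2 (14.8%) lay at 56.0 while age 4 replicate 4 (15.8%) and age 7 replicate 2 (16.1%) lay at 7.01 and -18.6. Age itself remains the difference that the design names.

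Chance was not excluded for the counts against age 2. At age 4, 3 of 35 splits of the 8 libraries into equal groups called as many genes as the real one (2979; highest other 5921). At age 7 it was 2 of 35 (4368; highest other 6479), and at age 9 it was 2 of 35 (2934; highest other 4665). The highest of the others each set age 2 replicate 1 with 3 older libraries, which points to a structure of the samples. For the gene lists, 16, 25 and 25 of 35 splits called as many lists as the real 13, 9 and 10 (highest other 18, 19 and 18), so chance was not excluded there either. For age 7 against age 4 only the real split gave 2 genes (1 of 35, the smallest share possible, with highest other 1). That share is under 0.05 for this comparison taken alone. It was not adjusted for the other comparisons, so it does not exclude chance. The margin is 1 gene, and edgeR called 0 with the replicate block, with no filter and without any 1 of the age 4 libraries. With 0 calls, all 35 of 35 splits were as large for age 9 against age 4 (highest other 1) and age 9 against age 7 (highest other 4). For any difference among the ages 2 of 100 drawn splits called as many, the real one included (3086), but 1 other gave 4958. This share is small but does not exclude chance. For the trend only the real order called as many (1 of 100, with 1992 and highest other 6), which argues against a chance order of the labels. That share does not show a steady change with age, as edgeR called 0 genes for a trend over ages 4, 7 and 9 alone.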

How the results depend on the processing

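The transcript counts, the fits without ribosomal RNA and mitochondrial genes and the trend over ages 4, 7 and 9 were chosen after seeing the data. Where a count moved by over 1.5 times the cause was not tested. Fits on fewer libraries have fewer degrees of freedom, and fits on age 2 with 1 other age also give the wider spread of age 2 more weight. On the 8 libraries of 2 ages alone edgeR called 0 genes for age 4 against age 2, 795 for age 7 against age 2, 987 for age 9 against age 2, 8 for age 9 against age 4 and 6 for age 9 against age 7. DESeq2 called 13, 108 and 62 genes for age 7 against age 4, age 9 against age 4 and age 9 against age 7, 5249 for any difference and 3034 for the trend. With limma voom the numbers were 7847, 8594 and 7805 against age 2 at ages 4, 7 and 9, then 0, 63 and 241 between the older ages, 8769 for any difference and 325 for the trend (203 rising, 122 falling); its weight for age 2 replicate 1 was 0.12. Age 7 against age 4 gave 0 genes without a filter on low counts and 0 with the replicate block. The trend had 1190 genes with the replicate block and 0 over ages 4, 7 and 9 alone. Whether the replicate numbers mark something shared by the fish was not settled. Same-number correlations lay between -0.22 and 0.412, with 9 of 24 over 0.1. Of 16 libraries 8 were closest to their own number, more than 4 unrelated numbers would give on average. This excess was not tested, so an effect of the number was neither shown nor excluded. The block also moved the higher share at age 4 from 35.8% to 44.7%, and its counts against age 2 were 3199, 4439 and 2790. Gene lists past the threshold were 0 at each age with the correlation estimated per list, and 6, 4 and 5 with fry. With the age 2 libraries split, shared calls averaged 12, 66.8 and 84.8 (0 to 69, 0 to 192 and 0 to 224). With 1 library left out in turn the counts spanned 1 to 7581 (age 4 against age 2), 1945 to 7941 (age 7 against age 2), 1157 to 7028 (age 9 against age 2), 0 to 3 (age 7 against age 4), 0 to 8 (age 9 against age 4), 0 to 1 (age 9 against age 7), 851 to 7616 (any difference) and 665 to 2715 (trend), and the lists 10 to 15, 9 to 10 and 9 to 14. The correlation of principal component 1 with age spanned -0.338 to -0.018 and the difference in spread -0.047 (reversed, without age 2 replicate 1) to 0.474. For named genes, 375 of 504 values were called; 0 of 12534 alternatives reversed a direction, 1363 lost a call and 213 gained one. Without age 2 replicate 3, 198 of the 375 calls were kept, and without age 2 replicate 1, 374. At this depth and spread, 2-fold changes were mostly missed.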

Other observations

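All tests in this part were chosen after the results had been seen.

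Genes of the egg varied between testes. The oocyte-associated genes btg4 and slbp2 spanned 0 to 28.7 CPM and 0.139 to 18.4 CPM within age 4, and 0 to 10.3 and 0.349 to 15.9 CPM within age 7. A hypothesis is that ovary and oocyte genes vary together between animals, which may reflect some cells with an oocyte-like transcript profile. Over the 12 libraries of ages 4, 7 and 9, btg4 correlated with the mean of the other ovary and oocyte list members at r = 0.951 (permutation p = 1e-05, adjusted 3.33e-05 over 10 relations) and Spearman's rho = 0.886 (p = 0.00027, adjusted 0.00054). Without the 2 libraries farthest from the median it was r = 0.908, and within ages 4, 7 and 9 it was 0.966, 0.982 and 0.844. The p of 1e-05 is the smallest that the permutations can give, and btg4 was picked because it varied. It was set against ovary and oocyte genes only, so whether the variation is particular to them was not settled.

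Transcript levels of insl3 and prok2 also differed between fish of 1 age. At age 7 the Leydig cell hormone insl3 ranged from 36.7 to 1278 CPM and prok2 from 3.67 to 152.2 CPM. A hypothesis is that Leydig cell and steroid synthesis genes vary together between animals, which could follow a reproductive state that differs between fish. Over the 12 libraries insl3 correlated with the mean of the other list members at r = 0.833 (permutation p = 0.00135, adjusted 0.0015) and rho = 0.734 (p = 0.00879, adjusted 0.00977), and at r = 0.822 without the 2 farthest libraries. Within ages 4, 7 and 9 it was 0.728, 0.979 and 0.832. For prok2, which is not on the list, r with the list mean was 0.900 (permutation p = 0.00028, adjusted 0.0004) and rho = 0.874 (p = 0.00044, adjusted 0.000733), with r = 0.880 without the 2 farthest. With the interferon gene ifit8, insl3 had r = 0.667 (permutation p = 0.0196, adjusted 0.0196) and rho = 0.566 (p = 0.0589, adjusted 0.0589), but r = 0.344 without the 2 farthest (0.784, 0.997 and 0.731 within ages 4, 7 and 9), so whether the variation is particular to Leydig genes was not settled. Neither the number nor the activity of Leydig cells was measured.

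Means of the lists per library gave a test that treats the fish as the unit. Between age 2 and the 12 older libraries 12 of 32 lists passed. Among them macrophage genes differed by 0.96 log2 (exact permutation over 1820 splits, p = 0.00055, adjusted p = 0.0176 over 32 lists), spermatogonia genes by -0.83 (exact p = 0.00165, adjusted 0.0176), flagellum genes by 1.89 (exact p = 0.00385, adjusted 0.0226) and interferon genes by 1.39 (exact p = 0.00440, adjusted 0.0226). The flagellum result rested on age 2 replicates 2 to 4 (1.96 to 2.61), as replicate 1 (5.01) lay within the older range (4.01 to 5.67). An older library in place of replicate 1 could give as small a p. This pass therefore does not show a difference shared by all fish of age 2. Lists that stand for other tissue in the sample also passed. Skeletal muscle genes differed by 0.51 (exact p = 0.0011, adjusted 0.0176) and kidney, gut and pancreas epithelium genes by -0.55 (exact p = 0.00989, adjusted 0.0352). The erythrocyte, lymphocyte, liver and ovary lists did not pass. A difference in tissue content between samples was thus not excluded. The hypothesis that interferon genes are higher at age 9 than at ages 4 and 7 was left undecided. Their mean was 1.15 higher, in 4 of 4 libraries of age 9, with an exact p = 0.00606 over 495 splits but an adjusted p = 0.097 over 32 lists, of which 0 passed.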
